A study of Mus musculus with 14 samples.

How the data were processed

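Total RNA of liver tumours was sequenced, per the labels, after extraction with a Qiagen kit and library preparation with an Illumina TruSeq kit. The authors deposited 2 tables of gene counts. Each value is a signal: per the labels and the deposited tables, HTSeq gene counts were scaled by DESeq, and Picard and the genome build mm10 are also named. The aligner, the annotation release and the versions of these tools are not given in the sources used here. The first table holds 10 libraries (4 sgGFP, 3 sgCul3 and 3 sgKeap1 tumours) and 16821 genes, while its header states 16820. The second holds 4 libraries (controls A and B, sgNrf2 A and B) and 16095 genes, with 4 more entries for reads assigned to no gene. Values were checked against whole reads: after removal of the 1 that the authors added to every entry of the first table, all values (100% in each library) were whole multiples of 1 step per library, to within 0.1 reads. Reads were recovered from these steps. The tables were scaled separately, so values were tested within a table and only fold changes were set side by side. Levels in the text are the scaled counts with the added 1 removed. Symbols that had been turned into dates or repeated were renamed by gene ID (23 and 24). Coordinates are those of GENCODE M21 on GRCm38, which holds 16769 and 16048 of the gene IDs, and 15777 genes are in both tables. Depth was 6333025 to 12008223 reads on genes in the first table and 17819333 to 20848578 in the second. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

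Groups were taken from the labels. Genes with a mean deposited value of at least 10 were tested with limma 3.58.1 in R 4.3.3 on log2 of the deposited value plus 1, with a mean-variance trend, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. The 3 groups of the first table shared 1 estimate of the spread. The comparisons were sgCul3 against sgGFP, sgKeap1 against sgGFP, the mean of both guides against sgGFP, sgKeap1 against sgCul3, and sgNrf2 against controls A and B. Controls A and B are labelled as repeats of sgGFP tumours 2 and 4, so agreement between the tables was measured against sgGFP tumours 1 and 3. Adjusted p-values in the text are those of limma unless camera, edgeR or DESeq2 is named. Where a group had no reads of a gene, its fold change is given as a bound against 3 reads over the group. Where it had 1 to 3, the ratio is given with its exact 95% interval for counting error, and means with an SD are per group.

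Gene lists (48, of textbook pathways and of markers of cell types) and the rule for named genes were fixed before the data were examined. The rule names Keap1, Cul3, Nfe2l2, Myc, Fn3k and Fn3krp in any case. For each comparison it names the 8 genes with the highest and the 8 with the lowest log2 fold change, among genes with a mean of at least 100, an adjusted p under 0.05 and groups that do not overlap, and if fewer than 3 pass in a direction, the 5 with the most extreme moderated t. It also names up to 4 members per list with the smallest adjusted p, and the 12 genes with the largest smallest change among those passing in the same direction in sgCul3, sgKeap1 and sgNrf2. Predicted genes and pseudogenes were skipped for the genes named by size. Of the lists and members the rule allows, those described were chosen after their values were seen, not every gene the rule names is described, and Ugt8a and Limk1 were named after their values were seen. Some genes are on more than 1 list. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, whose directional test asks whether the genes of a list move, on balance, one way. Of the 15, 16, 16, 15 and 19 lists called in the comparisons in the order above, 0 held in each with an estimated correlation after adjustment, and 4, 4, 5, 0 and 1 at its unadjusted p under 0.05. The directional test of fry called 5, 9, 8, 0 and 0 lists.

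Alternatives were a pseudocount of 5, no filter on low values, a mean of at least 50, quantile normalization, equal totals, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on recovered reads, the tumour number as a block, the 2 groups tested alone, and each library left out in turn. The labels do not say what the tumour numbers stand for. Since no guide tumour carries the number 4, the block takes sgGFP tumour 4 out of the comparisons with sgGFP. The deviations of same-numbered sgGFP and sgCul3 tumours from their group means correlated at 0.164, 0.175 and 0.314, each over 0.1, so in this comparison, and for these tumours in that of both guides together, the numbers were taken, from the data, to pair the tumours, and the values with the number as a block are given where they change a call. The overlap of sgCul3 and sgKeap1 effects was recomputed with separate controls for each and set against 100 simulations of unchanged groups. Removing the added 1, testing lists without 1 library or with the block, and list medians and ratios of genes with few reads without 1 library were added after the data were seen. For trends with transcript length, GC content and level, a lowess curve of span 0.3 was removed from the fold changes, and intervals of medians are 95% bootstrap intervals over genes from 2000 draws. The procedure was tested on simulated data with 200 changed genes at true folds of 2 and 4. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for tables and plots. Edits of the target genes, splicing and single tumour cells were left out, since gene counts do not hold them.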

Results

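Gene expression was measured by RNA sequencing in liver tumours of the mouse, hepatocellular carcinomas driven by MYC in which Cas9 and a guide RNA targeted 1 gene. Per the labels, 4 tumours carried a guide against GFP (sgGFP, the control), 3 a guide against Cul3 (sgCul3), 3 a guide against Keap1 (sgKeap1) and 2 a guide against the ETGE motif of NRF2 (sgNrf2). Beside sgNrf2 stand 2 control libraries, A and B, labelled as repeats of sgGFP tumours 2 and 4. KEAP1 binds the ETGE motif of the transcription factor NRF2 and presents it to the CUL3 ubiquitin ligase for degradation, and the labels describe the guides as ways to activate NRF2. The reads assigned to genes came to 11675999, 12008223, 10739965 and 11692240 in sgGFP tumours 1 to 4, 6333025, 10888667 and 10954518 in sgCul3 tumours 1 to 3, and 11317551, 6505295 and 6754550 in sgKeap1 tumours 1 to 3. They came to 17859275 and 17819333 in controls A and B and 20848578 and 19219106 in sgNrf2 tumours A and B. A count of 0 allows up to 0.144 to 0.474 CPM in these libraries, for counting error only. The 10 genes with most reads held 24.5% of the reads of sgKeap1 tumour 2 and 8.10% to 18.0% in the other libraries of its table. They held 15.6% and 18.9% in controls A and B against 7.94% and 9.09% in sgNrf2 tumours A and B.

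Transcripts of the targeted genes were measured first. Keap1 (ENSMUSG00000003308.15, GRCm38 chromosome 9, 21229730 to 21239361) had 462, 414 and 287 normalised reads in sgKeap1 tumours 1 to 3, and 599, 582, 707 and 721 in sgGFP tumours 1 to 4. The means were 387 ± 90.2 against 652 ± 71.8 (SD, n = 3 and 4), a log2 fold change of -0.77 ± 0.21 (SE). Its limma adjusted p was 0.048. The adjusted p of Keap1 was 0.078, 0.068, 0.12 and 0.081 without sgGFP tumours 1, 2, 3 or 4, 0.10 and 0.16 without sgKeap1 tumours 2 or 3, 0.053 with no filter on low values, 0.058 with edgeR and 0.066 with the 2 groups tested alone, in a range of 0.017 to 0.16 over its alternatives. In sgCul3 tumours 1 to 3 Keap1 had 1149.5, 907 and 823 reads, a log2 fold change of 0.55 ± 0.21 (adjusted p = 0.21). Cul3 (ENSMUSG00000004364.14, chromosome 1, 80264923 to 80340480) had 163, 426 and 676 reads in sgCul3 tumours 1 to 3 and 1372, 1247, 1202 and 935 in sgGFP tumours 1 to 4. Its means were 422 ± 256 against 1189 ± 184 (n = 3 and 4), a log2 fold change of -1.70 ± 0.39 that did not pass (limma adjusted p = 0.051, 0.0049 to 0.13 over the alternatives). In sgKeap1 tumours Cul3 had a log2 fold change of -0.62 ± 0.39 (adjusted p = 0.31). Nfe2l2 (ENSMUSG00000015839.6, chromosome 2, 75675513 to 75704641), which encodes NRF2, had 1486 and 1615 reads in sgNrf2 tumours A and B and 1844 and 1397 in controls A and B. The log2 fold change of Nfe2l2 was -0.05 ± 0.22 in sgNrf2 (adjusted p = 0.89), -0.06 ± 0.29 in sgCul3 (adjusted p = 0.94) and -0.17 ± 0.29 in sgKeap1 (adjusted p = 0.73). The ETGE codons, residues 79 to 82 of the 597-residue protein, lie in exon 2 at chromosome 2, 75679229 to 75679240. Gene counts hold no sequence, so the edits themselves were not analysed here. Myc, Fn3k and Fn3krp did not pass in any of these comparisons. Fn3k (GRCm38 chromosome 11, 121434913 to 121450491), a kinase that removes sugars from glycated proteins, had 83.6 ± 97.9 against 21.7 ± 12 reads in sgKeap1, 9.87 ± 13.8 against 21.7 ± 12 in sgCul3 and 42.7 ± 7.64 against 37.5 ± 14.9 in sgNrf2. Its relative Fn3krp had 338 ± 57.4 against 139 ± 18.0 reads in sgNrf2, a log2 fold change of 1.27 ± 0.30 (limma adjusted p = 0.075, 0.014 to 0.47 over the alternatives). Myc had log2 fold changes of -0.75 ± 0.51, -0.60 ± 0.51 and -0.06 ± 0.26 in sgCul3, sgKeap1 and sgNrf2 (adjusted p = 0.49, 0.45 and 0.90).

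**Figure D1:**
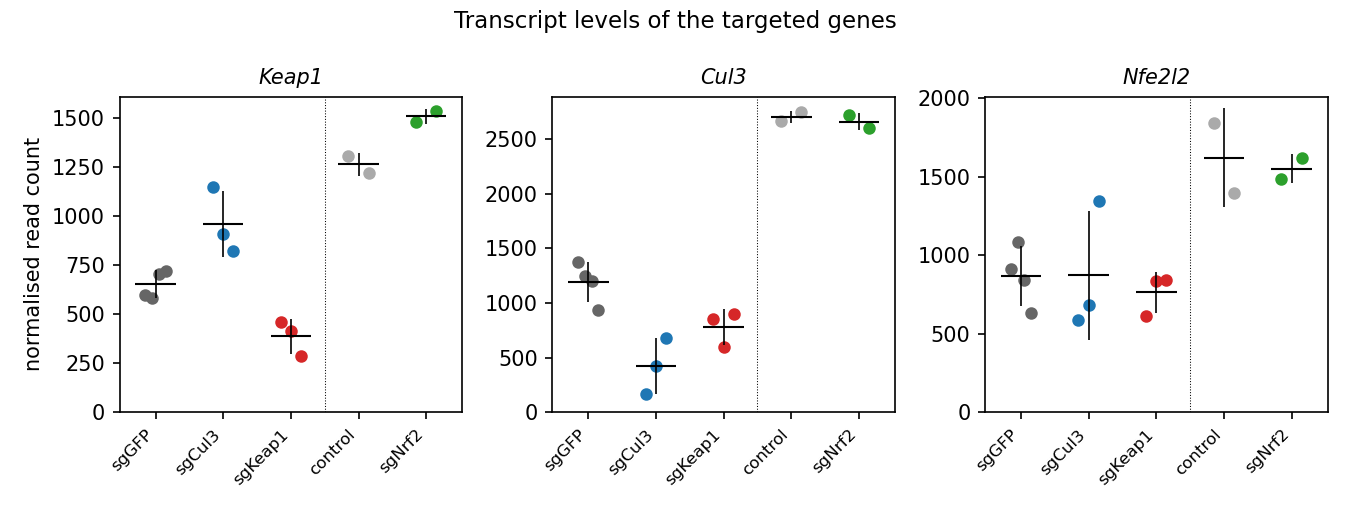
Normalised read counts of Keap1, Cul3 and Nfe2l2 per library, with the mean (horizontal line) and SD (vertical line) of each group. The dotted line parts the tables, which were scaled separately, and the sgKeap1 tumours had 287 to 462 Keap1 reads, below the 582 to 721 of the sgGFP tumours.

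The first comparison asked what changed when Cul3 was targeted (3 sgCul3 against 4 sgGFP tumours). Genes of the NRF2 response stood among the highest. Slc7a11 (ENSMUSG00000027737.10, GRCm38 chromosome 3, 49892526 to 50443614), the cystine importer, had 1799 ± 1045 against 8.34 ± 4.13 reads, and Cbr3, a carbonyl reductase, had 5305 ± 352 against 54.4 ± 34.6 (SD, n = 3 and 4). Their log2 fold changes were 7.38 ± 0.42 and 6.72 ± 0.35 (SE). The quinone reductase Nqo1 (6.19 ± 0.55), the sulfiredoxin Srxn1 (5.78 ± 0.35), the glutathione S-transferase Gsta1 (5.36 ± 0.82) and the acute phase gene Orm2 (5.10 ± 1.10) rose as well, with adjusted p of 7.9e-06 to 0.042 for these 6. The glutathione peroxidase Gpx2 and the transporter Slc5a4b had 1 to 3 reads over the sgGFP group, and the ratios to it were 535 (141 to 4207) and 318 (78.9 to 2353), with counting intervals, or 237 and 150 without sgCul3 tumour 1. Among the called genes ranked by the rule, with a mean of at least 100, the lowest log2 fold changes were those of Slc4a1, the red cell anion exchanger (-5.44 ± 0.83), Gatm, which starts creatine synthesis (-4.87 ± 0.65), the imprinted signalling adaptor Grb10 (-4.83 ± 0.37), and Slc4a9 (-4.31 ± 0.89). Tmed6 (-3.41 ± 0.61), Unc13d (-2.98 ± 0.54), Rap1gap2 (-2.80 ± 0.61) and the lipid droplet gene Plin5 (-2.76 ± 0.51) followed, with adjusted p of 1.2e-04 to 0.044 for these 8. Gpx2, Gsta1, Plin5, Rap1gap2, Slc4a9, Tmed6 and Unc13d did not pass without sgCul3 tumour 1 (adjusted p of 0.058 to 0.17), and Gpx2, Orm2 and Slc4a9 did not pass without sgCul3 tumour 2 (adjusted p of 0.076 to 0.13). Orm2, Plin5, Rap1gap2 and Slc4a9 did not pass without sgCul3 tumour 3 (adjusted p of 0.051 to 0.069), and Gpx2, Orm2, Rap1gap2 and Slc4a9 did not pass without sgGFP tumour 1 (adjusted p of 0.061 to 0.071). Gpx2, Orm2, Plin5, Rap1gap2, Slc4a9, Tmed6 and Unc13d did not pass without sgGFP tumour 2 (adjusted p of 0.055 to 0.090), and Gpx2, Orm2, Plin5, Rap1gap2, Slc4a9 and Unc13d did not pass without sgGFP tumour 3 (adjusted p of 0.065 to 0.11). Gpx2, Orm2, Plin5, Rap1gap2, Slc4a9 and Unc13d did not pass without sgGFP tumour 4 (adjusted p of 0.057 to 0.10). Slc4a9 did not pass with the added 1 removed (adjusted p = 0.063), Rap1gap2 did not pass with edgeR (adjusted p = 0.055), Gpx2 and Rap1gap2 did not pass among genes with a mean of at least 50 (adjusted p of 0.051 to 0.052), Gpx2 did not pass with a pseudocount of 5 (adjusted p = 0.069) and Gpx2 and Orm2 did not pass with the 2 groups tested alone (adjusted p of 0.068 to 0.080). Over every alternative, the adjusted p of these genes ranged from 4.2e-12 to 0.17. With the tumour number as a block, the adjusted p was 0.063 for Gpx2, 0.087 for Rap1gap2 and 0.053 for Unc13d.

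Of the 49 measured NRF2 target genes, 23 rose in sgCul3 and 26 did not pass, while 38 rose and 1 fell adjusted over the list alone. Their median log2 fold change was 1.47 (camera adjusted p = 2.8e-28, or adjusted p = 0.086 with an estimated correlation). They include Gclc (2.93 ± 0.29), Gsr (1.93 ± 0.26) and Txnrd1 (2.14 ± 0.22), which make glutathione and keep glutathione and thioredoxin reduced, and Pgd of the pentose phosphate pathway (2.0 ± 0.29), with adjusted p of 8.0e-04 to 0.0069. Txnip, the inhibitor of thioredoxin, fell (-1.85 ± 0.26, adjusted p = 0.0061). Of 23 glutathione S-transferase genes 8 rose, or 14 adjusted over the list alone, among them Gstm2 (4.20 ± 0.50) and Gstm4 (2.96 ± 0.34), at a median of 1.47 (camera adjusted p = 2.5e-07, or adjusted p = 0.33 with an estimated correlation). These genes have close copies, so reads may be shared between them. Of 19 bile acid synthesis genes 2 rose, or 4 adjusted over the list alone: Cyp7b1 (4.95 ± 0.42) and Cyp8b1 (3.22 ± 0.51). The list itself did not pass (camera adjusted p = 0.64), and its median of -0.15 and mean of 0.51 differ in sign. Of 22 heat shock genes 1 rose, Hspb8 (4.07 ± 0.59), or 6 adjusted over the list alone, at a median of 0.56 (camera adjusted p = 6.8e-05, or adjusted p = 0.086 with an estimated correlation). Cyclin D1, Ccnd1, rose (3.41 ± 0.54), and Tspan8 (4.93 ± 0.63) and Ddit4l (3.63 ± 0.39), listed among the cholangiocyte and progenitor markers, Cbr1 (3.03 ± 0.47) and Ugp2 (2.20 ± 0.28) rose too (adjusted p of 0.0011 to 0.010). Of 12 erythroid markers 5 fell, or 12 adjusted over the list alone, at a median of -2.40 (camera adjusted p = 3.0e-11, or adjusted p = 0.33 with an estimated correlation). The 15 neutrophil markers had a median of -1.73 (camera adjusted p = 1.8e-05, or adjusted p = 0.77 with an estimated correlation), and limma called 0 of them lower over all genes (9 at an unadjusted p under 0.05), edgeR 0 and DESeq2 4, and 5 fell adjusted over the list alone. Of the NRF2 target genes, 12 rose without sgCul3 tumour 1 and 15 without sgGFP tumour 3. Of the glutathione S-transferases, 4 rose without sgCul3 tumour 1. Of the erythroid markers, 1 fell without sgCul3 tumour 1, 2 without sgGFP tumours 1, 2, 3 or 4 or sgCul3 tumour 3 and 8 without sgCul3 tumour 2. Of the neutrophil markers, 3 fell without sgCul3 tumour 2. Erythroid markers had a median of -1.44 without sgCul3 tumour 3. Neutrophil markers had a median of -2.62 without sgCul3 tumour 2 and -0.97 without sgCul3 tumour 3. With the tumour number as a block, 1 of the neutrophil markers fell. With the 2 groups tested alone, 15 of the NRF2 target genes rose.

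In sgCul3, limma called 176 genes higher and 111 lower among 13045 tested, edgeR 169 and 77, and DESeq2 479 and 447. The groups did not overlap in 16.2% of the tested genes, against 5.71% by chance. The numbers higher and lower were 113 and 86 without sgGFP tumour 1, 85 and 34 without sgGFP tumour 2, 75 and 31 without sgGFP tumour 3, 96 and 46 without sgGFP tumour 4, 44 and 21 without sgCul3 tumour 1 and 83 and 70 without sgCul3 tumour 2. With the 2 groups tested alone they were 96 and 72, and for genes with a mean of at least 50 they were 115 and 47. Here and throughout, p-values measure only the spread between these samples, whose labels name separate tumours without saying whether these come from separate animals.

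The sgKeap1 tumours (n = 3) were compared with the same 4 sgGFP tumours. Slc7a11 rose from 8.34 ± 4.13 to 3701 ± 1147 reads and Nqo1 (ENSMUSG00000003849.8, GRCm38 chromosome 8, 107388225 to 107403206) from 52.1 ± 42.8 to 5927 ± 1373 (SD). The log2 fold changes were 8.53 ± 0.42 for Slc7a11, 7.11 ± 0.55 for Nqo1, 6.97 ± 0.35 for Srxn1 and 6.96 ± 0.35 for Cbr3 (SE). The metallothionein Mt3 (7.74 ± 0.88) and the P450 genes Cyp2a5 (7.72 ± 0.62) and Cyp2a4 (6.86 ± 1.35), close copies whose reads may be shared, rose as well (adjusted p of 2.2e-06 to 0.015 for these 7). For Gpx2 and Slc5a4b, with 1 to 3 reads over sgGFP, the ratios were 1367 (360.4 to 10752) and 808 (200.2 to 5971), with counting intervals, that of Slc5a4b 509 without sgKeap1 tumour 2. Among the called genes ranked by the rule, with a mean of at least 100, the lowest values were those of Slc4a1 (-5.57 ± 0.83), the bile acid binding protein gene Fabp6 (-5.51 ± 0.84), Slc4a9 (-5.09 ± 0.89), Tmed6 (-5.01 ± 0.61), the microtubule gene Map2 (-4.51 ± 0.36), Rap1gap2 (-4.15 ± 0.61), Grb10 (-3.95 ± 0.37) and the growth factor binding protein gene Igfbp1 (-3.60 ± 0.71), with adjusted p of 7.6e-05 to 0.015. The adjusted p of Igfbp1 was 0.057 and 0.053 without sgKeap1 tumours 2 or 3, in a range of 2.6e-05 to 0.057 over its alternatives.

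Of the 49 NRF2 target genes, 33 rose in sgKeap1 and 16 did not pass, or 40 rose and 1 fell adjusted over the list alone, at a median log2 fold change of 2.19 (camera adjusted p = 1.4e-28, or adjusted p = 0.14 with an estimated correlation). Gclc and Gclm, the 2 subunits of the enzyme that starts glutathione synthesis, rose by 3.85 ± 0.29 and 2.34 ± 0.32 on the log2 scale. Gsr (2.59 ± 0.26) and Txnrd1 (2.19 ± 0.22), the NADPH producers Pgd (2.15 ± 0.29) and Me1 (2.59 ± 0.36), catalase, Cat (2.53 ± 0.36), and the export pumps Abcc3 (3.4 ± 0.46) and Abcc4 (4.50 ± 0.58) rose with them. Adjusted p of these 9 genes was 6.3e-05 to 0.0027. Of 21 genes of glutathione synthesis and peroxide reduction 8 rose and 1 fell, or 11 and 3 adjusted over the list alone (camera adjusted p = 9.1e-05, or adjusted p = 0.27 with an estimated correlation). Of 23 glutathione S-transferases 11 rose, or 15 adjusted over the list alone, among them Gstm4 (4.10 ± 0.34) and Gsta2 (4.25 ± 0.48), at a median of 2.01 (camera adjusted p = 1.1e-07, or adjusted p = 0.27 with an estimated correlation). Of 18 glucuronosyl- and sulfotransferases 6 rose, or 7 adjusted over the list alone, among them Ugt2b35 (3.4 ± 0.43) and Ugt2b1 (4.32 ± 0.75) (camera adjusted p = 0.0039, or adjusted p = 0.85 with an estimated correlation). Of 26 heme and iron genes 6 rose, or 8 adjusted over the list alone (camera adjusted p = 0.033, or adjusted p = 0.78 with an estimated correlation). These include the heme transporter Slc48a1 (3.0 ± 0.33), the biliverdin reductase Blvrb (3.36 ± 0.39), hepcidin, Hamp (3.27 ± 0.51), and ferritin light chain, Ftl1 (1.59 ± 0.30). Of 19 bile acid synthesis genes 5 rose, or 5 rose and 1 fell adjusted over the list alone, among them Cyp7b1 (5.82 ± 0.42), Cyp8b1 (3.86 ± 0.51) and Akr1c14 (3.72 ± 0.56) (camera adjusted p = 0.033, or adjusted p = 0.86 with an estimated correlation). Of the glutathione S-transferases, 7 rose without sgKeap1 tumour 3. Of the glucuronosyl- and sulfotransferases, 3 rose without sgGFP tumour 3 or sgKeap1 tumour 3. Of the bile acid synthesis genes, 3 rose without sgGFP tumours 1 or 2 or sgKeap1 tumours 2 or 3. In camera the heme and iron genes did not pass without sgGFP tumour 1 or sgKeap1 tumour 2 (adjusted p = 0.054 and 0.090), and the bile acid synthesis genes did not pass without sgGFP tumours 1 or 2 or sgKeap1 tumour 2 (adjusted p = 0.12, 0.063 and 0.22).

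Other genes that rose in sgKeap1 were Ccnd1 (4.42 ± 0.54), Hspb8 (5.07 ± 0.59), Ugp2 (3.20 ± 0.28) and Cbr1 (3.64 ± 0.47), the interferon-induced Mx1 (4.73 ± 0.68) and the neurexin Nrxn2 (5.33 ± 0.40), with adjusted p of 6.3e-05 to 0.0028. The oxygen sensor Egln1 fell (-2.06 ± 0.37, adjusted p = 0.0086), as did Sall4, a transcription factor of fetal liver (-5.35 ± 0.59, adjusted p = 6.3e-04). AF529169 had reads in sgGFP but in none of the sgKeap1 and sgCul3 tumours, which makes it at least 70.2-fold and at least 98.6-fold lower, against 3 reads over each group. Markers of blood cells were low in the same tumours. Of 15 neutrophil markers 9 fell, or 13 adjusted over the list alone, at a median of -2.99 (camera adjusted p = 1.8e-08, or adjusted p = 0.52 with an estimated correlation). Mpo, the myeloperoxidase of neutrophil granules, had 1.91 ± 1.04 against 112 ± 78.3 reads (-4.68 ± 0.87, adjusted p = 0.011), and the elastase Elane was at a ratio of 51.6 between sgGFP and sgKeap1 (counting interval 11.3 to 337, or 32.8 without sgGFP tumour 2). Of 12 erythroid markers 6 fell, or 9 adjusted over the list alone, at a median of -2.43 (camera adjusted p = 2.1e-07, or adjusted p = 0.52 with an estimated correlation). Of 15 markers of cholangiocytes and progenitors 4 rose, or 5 rose and 1 fell adjusted over the list alone, at a median of 1.57, and the list did not pass (camera adjusted p = 0.11, or adjusted p = 0.85 with an estimated correlation). Of the erythroid markers, 3 fell without sgGFP tumour 3 or sgKeap1 tumour 3. Of the neutrophil markers, 3 fell without sgKeap1 tumour 2 and 4 without sgKeap1 tumour 3. Of the cholangiocyte and progenitor markers, 1 rose without sgGFP tumour 3 or sgKeap1 tumour 3 and 2 without sgGFP tumours 1 or 4 or sgKeap1 tumours 1 or 2. In camera the cholangiocyte and progenitor markers passed without sgKeap1 tumour 2 (adjusted p = 0.045). Cholangiocyte and progenitor markers had a median of 0.85 without sgGFP tumour 3, 0.57 without sgGFP tumour 4 and 0.92 without sgKeap1 tumour 1. Within the group, sgKeap1 tumour 2 differed from the mean of tumours 1 and 3 by a median of 3.91 (log2) over the liver P450 genes, 1.31 over the glucuronosyl- and sulfotransferases and 1.33 over urea cycle and amino acid genes.

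In sgKeap1, limma called 581 genes higher and 439 lower among 13045 tested, edgeR 610 and 349, and DESeq2 1181 and 962. The groups did not overlap in 25.8% of the tested genes, against 5.71% by chance. The numbers higher and lower were 362 and 237 without sgGFP tumour 1, 428 and 243 without sgGFP tumour 2, 274 and 129 without sgGFP tumour 3, 814 and 688 without sgKeap1 tumour 1, 231 and 141 without sgKeap1 tumour 2 and 201 and 113 without sgKeap1 tumour 3. Scaling to equal totals moved the median of all genes from -0.01 to -0.21 and gave 365 genes higher and 386 lower. Relative to that median, the NRF2 target genes were at 2.19. Equal totals shift all genes of a library by nearly the same log2 amount. This value thus restates the main fit and does not test the scaling.

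**Figure D2:**
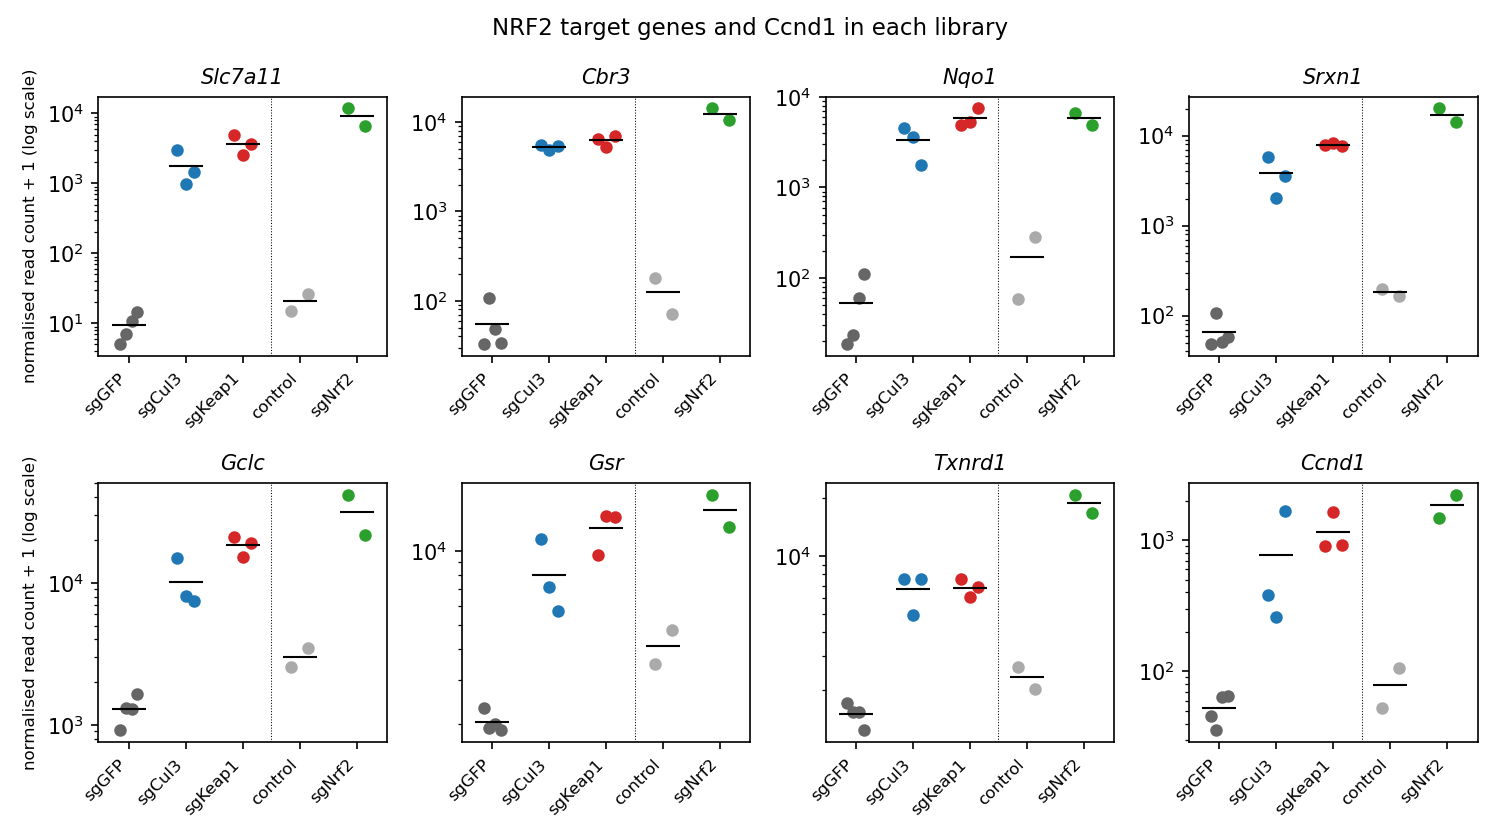
Normalised read counts plus 1 (log axis) of 7 NRF2 target genes and Ccnd1 in each library, with horizontal lines at the group means. The dotted line parts the separately scaled tables, and Slc7a11 lies between 983 and 4862 reads in the sgCul3 and sgKeap1 tumours and between 4.05 and 13.4 in the sgGFP tumours.

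Taking the mean of the sgKeap1 and sgCul3 groups against sgGFP (6 and 4 tumours) asked what tumours with either guide had in common on average. Among the called genes ranked by the rule, with a mean of at least 100, the highest log2 fold changes were those of Slc7a11 (7.95 ± 0.35), Cbr3 (6.84 ± 0.29), Nqo1 (6.65 ± 0.46), Srxn1 (6.37 ± 0.30), Gsta1 (6.10 ± 0.70) and Cyp2a5 (5.83 ± 0.52), and the ratios of Gpx2 and Slc5a4b to their 1 to 3 sgGFP reads were 951 (251 to 7479) and 563 (139.5 to 4162). The lowest under the same rule were those of Slc4a1 (-5.51 ± 0.70), Slc4a9 (-4.70 ± 0.75), Grb10 (-4.39 ± 0.31), Tmed6 (-4.21 ± 0.51), Fabp6 (-4.14 ± 0.71), Gatm (-3.63 ± 0.55), Rap1gap2 (-3.47 ± 0.52) and Alas2 (-3.12 ± 0.60), the last of these the heme synthesis gene of red cells. Adjusted p over these genes was 7.6e-07 to 0.012, and each of them passed with any 1 library left out. Of the NRF2 target genes 35 rose and 1 fell, or 40 and 1 adjusted over the list alone, at a median of 2.08 (camera adjusted p = 1.1e-29, or adjusted p = 0.12 with an estimated correlation), with Gclc (3.39 ± 0.25), Gsr (2.26 ± 0.22) and Txnrd1 (2.16 ± 0.18) among them. Of the glutathione S-transferases 14 rose, the same number adjusted over the list alone, at a median of 1.68 (camera adjusted p = 6.7e-08, or adjusted p = 0.28 with an estimated correlation). Of 34 fatty acid oxidation genes 7 fell and 1 rose, or 8 and 2 adjusted over the list alone, at a median of -0.37 (camera adjusted p = 0.028, or adjusted p = 0.85 with an estimated correlation). In sgCul3 alone 3 of them fell, or 8 fell and 1 rose adjusted over the list alone, at a median of -0.59 (camera adjusted p = 1.7e-05, or adjusted p = 0.77 with an estimated correlation). In sgKeap1 alone 3 fell and 2 rose, or 8 and 4 adjusted over the list alone, and the median of -0.08, -0.33 to 0.08 with 1 library left out, did not pass (camera adjusted p = 0.62, or adjusted p = 0.95 with an estimated correlation). The test of sgKeap1 against sgCul3 put them at 0.59 (camera adjusted p = 5.5e-05, or adjusted p = 0.83 with an estimated correlation). Those that fell for both guides together include Cpt1a, which admits fatty acids to mitochondria (-1.51 ± 0.30), and the fasting regulator Creb3l3 (-1.17 ± 0.24), while the p53 target Sesn1 (-1.15 ± 0.22) and Egln1 (-1.59 ± 0.31) fell as well (adjusted p of 0.011 to 0.014). Of the neutrophil markers 9 fell, or 11 adjusted over the list alone, with Ngp at -4.60 ± 0.72 (adjusted p = 0.0043), and of the erythroid markers 7, or 12, with medians of -2.33 and -2.41. The adjusted p of these marker lists was 7.2e-08 and 1.7e-09 in camera, and adjusted p = 0.68 and 0.37 with an estimated correlation. Of the fatty acid oxidation genes, 2 fell without sgGFP tumour 3, 3 without sgGFP tumour 2 and 4 without sgGFP tumour 4, sgCul3 tumour 1 or sgKeap1 tumour 3. Of the erythroid markers, 11 fell without sgCul3 tumour 2. Of the neutrophil markers, 4 fell without sgGFP tumours 1 or 2 or sgCul3 tumour 1 and 5 without sgGFP tumour 4 or sgKeap1 tumours 2 or 3. Of the fatty acid oxidation genes in sgCul3 alone, 0 (7 at an unadjusted p under 0.05) fell without sgCul3 tumour 1, 0 (8 at an unadjusted p under 0.05) without sgGFP tumour 2, 0 (10 at an unadjusted p under 0.05) without sgGFP tumour 3 and 1 without sgGFP tumour 4 or sgCul3 tumour 2. Of the fatty acid oxidation genes in sgKeap1 alone, 0 (7 at an unadjusted p under 0.05) fell without sgKeap1 tumour 3, 0 (8 at an unadjusted p under 0.05) without sgGFP tumour 2, 0 (9 at an unadjusted p under 0.05) without sgGFP tumour 3 and 1 without sgGFP tumour 1 or sgKeap1 tumours 1 or 2. Their median in sgCul3 was -0.31 without sgCul3 tumour 1, and with the tumour number as a block 5 of them fell there. The 1 NRF2 target gene that fell for both guides together did not pass with that block. In camera the fatty acid oxidation genes did not pass without sgGFP tumour 2, sgCul3 tumour 1 or sgKeap1 tumours 1 or 3 (adjusted p = 0.10, 0.068, 0.13 and 0.055).

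For both guides together, limma called 570 genes higher and 416 lower among 13045 tested, edgeR 543 and 474, and DESeq2 1105 and 947. The groups did not overlap in 9.23% of the tested genes, against 0.952% by chance. The numbers higher and lower were 378 and 225 without sgGFP tumour 2, 257 and 138 without sgGFP tumour 3, 442 and 263 without sgGFP tumour 4, 320 and 214 without sgCul3 tumour 1, 349 and 254 without sgCul3 tumour 2, 882 and 671 without sgCul3 tumour 3 and 315 and 232 without sgKeap1 tumour 3. Both guide groups were measured against the same sgGFP tumours, which alone makes their fold changes correlate. Across 13045 genes, which are not independent replicates, Pearson's r of the sgCul3 and sgKeap1 log2 fold changes was 0.762 and Spearman's rho 0.692, while 100 simulations of unchanged groups with shared controls gave a mean r of 0.416. The covariance was 0.576 against a simulated 0.0966, a difference of 0.479. Genes called in both numbered 142 higher and 80 lower. Independent calls would give 7.84 and 3.74, a reference that leaves out the shared controls and so lies too low. The simulations drew each tumour independently, without the pairing of same-numbered tumours. With separate control tumours for each guide, in the 6 ways of dividing the sgGFP tumours, r was 0.391 to 0.717, the covariance 0.377 to 0.561, and 22 to 90 genes were higher and 8 to 44 lower in both. Levels correlated at 0.963 between sgGFP tumours 1 and 2 and 0.971 between 3 and 4, against 0.899 to 0.937 otherwise. Parting 1 and 2 from 3 and 4 gave r of 0.459 and 0.391, with 90 and 89 genes higher and 34 and 44 lower in both. The other ways, at r of 0.542 to 0.717, leave like tumours on both sides.

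The sgKeap1 and sgCul3 tumours were also tested against each other (n = 3 and 3), for differences between the ways of activating NRF2. The copper oxidase gene Heph, which acts in iron export, had 467 ± 163 against 17.1 ± 17.0 reads in sgKeap1 against sgCul3, the meiotic cohesin gene Rec8 270 ± 71.0 against 26.1 ± 15.4 and the KIT ligand gene Kitl 619 ± 57.7 against 176 ± 35.9 (SD). Their log2 fold changes were 4.96 ± 0.68, 3.38 ± 0.40 and 1.82 ± 0.21 (SE, adjusted p = 0.029, 0.014 and 0.014). Ugt8a, named after its values were seen since it completes the 8 calls, was at a ratio of 97.5 (33.4 to 473), with a counting interval, or 41.6 without sgKeap1 tumour 2. Lower in sgKeap1 were Map2 (-3.14 ± 0.39), the synaptic scaffold gene Bsn (-2.81 ± 0.27), Fam169a (-2.77 ± 0.39) and Glipr2 (-1.74 ± 0.21), with adjusted p of 0.0054 to 0.030. Each of these 8 genes passed in sgKeap1 against sgGFP, and in sgCul3 against sgGFP the log2 fold changes ran from -1.37 (Map2, adjusted p = 0.084) to 0.91 (Heph, adjusted p = 0.51). Cyp2a5 was at 3.78 ± 0.66 and did not pass (adjusted p = 0.099). The median log2 fold change of the NRF2 target genes was 0.61 (camera adjusted p = 3.2e-08, or adjusted p = 0.83 with an estimated correlation), with 1 gene higher adjusted over the list alone, and that of the cell cycle genes was -0.47 (camera adjusted p = 8.4e-09, or adjusted p = 0.83 with an estimated correlation). The neutrophil markers were at -1.39 (camera adjusted p = 7.0e-05, or adjusted p = 0.83 with an estimated correlation), but at -0.43 (camera adjusted p = 0.11) without sgCul3 tumour 2. Their mean log2 level was 5.99 in that tumour, 3.8 and 3.22 in sgCul3 tumours 1 and 3 and 2.75 to 3.29 in the sgKeap1 tumours. In this comparison limma called 4 genes higher and 4 lower among 13045 tested, edgeR 3 and 3, and DESeq2 64 and 40. The groups did not overlap in 15.8% of the tested genes, against 10% by chance. At an unadjusted p under 0.05 limma found 1315 genes. The numbers higher and lower were 0 and 1 without sgCul3 tumour 1, 2 and 2 without sgCul3 tumour 3, 0 and 2 without sgKeap1 tumour 1, 5 and 2 without sgKeap1 tumour 2 and 0 and 0 without sgKeap1 tumour 3. Scaling to equal totals moved the median of all genes from -0.00 to -0.24, relative to which the NRF2 target genes were at 0.61 and the cell cycle genes at -0.47. Since this scaling shifts all genes nearly alike, these 2 values restate the main fit and do not test the scaling. With the 2 groups tested alone limma called 0 and 0, and 1164 genes had an unadjusted p under 0.05, against 1012 without sgKeap1 tumour 3, 711 without sgKeap1 tumour 2, 2035 without sgKeap1 tumour 1, and 1046, 1454 and 844 without sgCul3 tumours 1, 2 or 3. Fam169a, Glipr2, Heph, Kitl, Map2, Rec8 and Ugt8a did not pass without sgCul3 tumour 1 (adjusted p of 0.086 to 0.13), and Map2 and Ugt8a did not pass without sgCul3 tumour 2 (adjusted p of 0.052 to 0.071). Fam169a, Glipr2, Heph and Ugt8a did not pass without sgCul3 tumour 3 (adjusted p of 0.068 to 0.14), and Fam169a, Heph, Kitl, Map2, Rec8 and Ugt8a did not pass without sgKeap1 tumour 1 (adjusted p of 0.080 to 0.10). Fam169a, Heph and Map2 did not pass without sgKeap1 tumour 2 (adjusted p of 0.054 to 0.13), and Bsn, Fam169a, Glipr2, Heph, Kitl, Map2, Rec8 and Ugt8a did not pass without sgKeap1 tumour 3 (adjusted p of 0.059 to 0.21). Fam169a and Heph did not pass with edgeR (adjusted p of 0.053 to 0.11), Glipr2 and Kitl did not pass at equal totals (adjusted p of 0.051 to 0.091), Heph did not pass among genes with a mean of at least 50 (adjusted p = 0.069) and Bsn, Fam169a, Glipr2, Heph, Kitl, Map2, Rec8 and Ugt8a did not pass with the 2 groups tested alone (adjusted p of 0.13 to 0.15). Over every alternative, the adjusted p of these genes ranged from 1.5e-15 to 0.21.

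The last comparison asked what changed when the ETGE motif of NRF2 was targeted (2 sgNrf2 tumours against controls A and B). Slc7a11 had 9286 ± 3645 against 19.7 ± 7.99 reads and Cbr3 12462 ± 2538 against 124 ± 74.9 (SD, n = 2 and 2), log2 fold changes of 8.81 ± 0.43 and 6.77 ± 0.47 (SE). Cyp7b1, a hydroxylase of bile acid synthesis, rose by 7.51 ± 0.38 on the log2 scale. Gpx2 and Slc5a4b had 1 to 3 reads over the controls, and the ratios were 2198 (608 to 18147) and 387 (136 to 1928), with counting intervals. The ubiquitin ligase adaptor Asb9 and the tight junction gene Cldn18 had no reads in the controls and were at least 216-fold and at least 212-fold higher, against 3 reads over the group. Cldn18 had 670 reads in sgNrf2 tumour A and 76.0 in B, and it was at least 43.3-fold higher without A and at least 381-fold without B. Among the lowest were the growth factor binding protein gene Igfbp2 (-9.88 ± 0.41), Fabp6 (-8.00 ± 0.44), the imprinted noncoding RNA Meg3 (-6.95 ± 0.63) and the fatty acid hydroxylase Cyp4a14 (-6.76 ± 1.14), with adjusted p of 0.012 to 0.047 for these 7 named with a log2 fold change. Sall4 had no reads in sgNrf2 and was at least 226-fold lower, or at least 147-fold without control B, and AF529169 was at least 31.1-fold lower. The ratios of the controls to sgNrf2 were 741 (213 to 6348) for Slc4a9, 448 (124 to 3697) for Epb41l4a and 527 (91.0 to 20027) for Mirg, a noncoding RNA of the Meg3 locus, with 1 to 3 reads over sgNrf2, and 287 and 317 for the last 2 without control B. Cldn18 did not pass without control B (adjusted p = 0.066), and AF529169, Cldn18 and Cyp4a14 did not pass without sgNrf2 tumour A (adjusted p of 0.095 to 0.12). AF529169, Cyp4a14 and Mirg did not pass without sgNrf2 tumour B (adjusted p of 0.059 to 0.098). Cldn18 and Cyp4a14 did not pass with edgeR (adjusted p of 0.056 to 0.073), Cldn18 did not pass among genes with a mean of at least 50 (adjusted p = 0.059) and Cldn18 did not pass with a pseudocount of 5 (adjusted p = 0.053). Over every alternative, the adjusted p of these genes ranged from 2.7e-14 to 0.12.

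Of the 49 NRF2 target genes, 20 rose in sgNrf2 and 29 did not pass, or 31 rose and 1 fell adjusted over the list alone, at a median log2 fold change of 1.84 (camera adjusted p = 6.8e-11, or adjusted p = 0.69 with an estimated correlation). They include Srxn1 (6.54 ± 0.25), Nqo1 (5.47 ± 0.75), Gclc (3.34 ± 0.38), Gsr (1.83 ± 0.27) and Txnrd1 (3.0 ± 0.24). Of 23 glutathione S-transferases 3 rose and 2 fell, or 11 and 2 adjusted over the list alone, at a median of 1.28 (camera adjusted p = 0.042, or adjusted p = 0.69 with an estimated correlation). Of 19 bile acid synthesis genes 6 rose and 1 fell, or 7 and 1 adjusted over the list alone, with Cyp8b1 at 6.45 ± 0.39 and Akr1c6, which has close copies, at 6.62 ± 0.42 (list: camera adjusted p = 0.054). Ugt2b35 (3.27 ± 0.26), Ccnd1 (4.60 ± 0.43), Nrxn2 (5.83 ± 0.66) and Mx1 (5.43 ± 0.90) rose, and the sulfotransferase Sult2a1 (-5.09 ± 0.42) and Igfbp1 (-4.71 ± 0.38) fell. Adjusted p of the 13 genes named here was 0.012 to 0.047. Of the NRF2 target genes, 8 rose without sgNrf2 tumour B and 10 without sgNrf2 tumour A. Of the glutathione S-transferases, 0 (11 at an unadjusted p under 0.05) rose without sgNrf2 tumour B, 1 without sgNrf2 tumour A, 7 without control A and 10 without control B. Of the bile acid synthesis genes, 3 rose without sgNrf2 tumour B. In camera the glutathione S-transferases did not pass without control A (adjusted p = 0.23), and the bile acid synthesis genes passed without sgNrf2 tumour A (adjusted p = 0.013). Glutathione S-transferases had a median of 0.77 without control A. Gclc did not pass without control B (adjusted p = 0.050), and Gsr, Mx1, Nqo1 and Nrxn2 did not pass without sgNrf2 tumour A (adjusted p of 0.062 to 0.20). Ccnd1, Gsr, Mx1, Nqo1, Nrxn2 and Txnrd1 did not pass without sgNrf2 tumour B (adjusted p of 0.051 to 0.12). Mx1 did not pass with edgeR (adjusted p = 0.054). Over every alternative, the adjusted p of these genes ranged from 2.7e-21 to 0.20.

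Genes of protein synthesis and respiration had negative medians in sgNrf2. Of 42 cytosolic ribosomal protein genes 7 fell, or 27 adjusted over the list alone, at a median of -1.13 (camera adjusted p = 1.0e-10, or adjusted p = 0.69 with an estimated correlation), with Rps14 at -1.92 ± 0.22 and Rps24 at -1.68 ± 0.22. Of 36 oxidative phosphorylation genes 10 fell, or 25 adjusted over the list alone, at a median of -1.16 (camera adjusted p = 1.0e-09, or adjusted p = 0.69 with an estimated correlation), with Uqcrq at -2.01 ± 0.20 and Ndufb8 at -1.75 ± 0.24. These are short transcripts, some with processed copies in the genome, and over all genes the fold change had a Spearman correlation of 0.308 with transcript length. Of 34 fatty acid oxidation genes 7 fell, or 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 3.4e-04, or adjusted p = 0.69 with an estimated correlation), with Acot2 at -3.5 ± 0.31. Of 34 urea cycle and amino acid genes 5 fell and 1 rose, or 17 and 1 adjusted over the list alone (camera adjusted p = 5.2e-05, or adjusted p = 0.69 with an estimated correlation), with Ass1 of the urea cycle at -1.99 ± 0.20. Of 12 erythroid markers 9 fell, or 11 adjusted over the list alone, at a median of -3.63 (camera adjusted p = 2.1e-08, or adjusted p = 0.69 with an estimated correlation), with Slc4a1 (-5.19 ± 0.67) and the beta globin Hbb-bs (-3.77 ± 0.38). Of 15 neutrophil markers 4 fell, or 13 adjusted over the list alone, at a median of -4.08 (camera adjusted p = 1.3e-07, or adjusted p = 0.69 with an estimated correlation), with Retnlg (-5.06 ± 0.42) and S100a8 (-5.22 ± 0.66). Adjusted p of these 10 genes was 0.024 to 0.041. Of 16 markers of cholangiocytes and progenitors 1 rose, or 4 adjusted over the list alone, at a median of 2.11 (camera adjusted p = 0.0016, or adjusted p = 0.69 with an estimated correlation). Of the ribosomal protein genes, 0 (16 at an unadjusted p under 0.05) fell without sgNrf2 tumour A, 0 (18 at an unadjusted p under 0.05) without sgNrf2 tumour B, 15 without control B and 23 without control A. Of the oxidative phosphorylation genes, 0 (19 at an unadjusted p under 0.05) fell without sgNrf2 tumours A or B and 27 without control A. Of the fatty acid oxidation genes, 0 (12 at an unadjusted p under 0.05) fell without sgNrf2 tumour B and 2 without sgNrf2 tumour A. Of the urea cycle and amino acid genes, 0 (13 at an unadjusted p under 0.05) fell without sgNrf2 tumour A, 0 (16 at an unadjusted p under 0.05) without sgNrf2 tumour B and 21 without control A. Of the erythroid markers, 2 fell without control B and 3 without sgNrf2 tumours A or B. Of the cholangiocyte and progenitor markers, 0 (4 at an unadjusted p under 0.05) rose without sgNrf2 tumour A, 0 (8 at an unadjusted p under 0.05) without sgNrf2 tumour B, 3 without control B and 7 without control A. In camera the cholangiocyte and progenitor markers did not pass without control B (adjusted p = 0.0502). Cholangiocyte and progenitor markers had a median of 0.97 without control B and 1.24 without sgNrf2 tumour A. Hbb-bs, S100a8 and Slc4a1 did not pass without control B (adjusted p of 0.051 to 0.053), and Ass1, Ndufb8, Rps14, Rps24, Slc4a1 and Uqcrq did not pass without sgNrf2 tumour A (adjusted p of 0.059 to 0.24). Acot2, Ass1, Ndufb8, Retnlg, Rps14, Rps24, Slc4a1 and Uqcrq did not pass without sgNrf2 tumour B (adjusted p of 0.051 to 0.16). Over every alternative, the adjusted p of these genes ranged from 1.9e-19 to 0.24.

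In sgNrf2, limma called 266 genes higher and 351 lower among 13989 tested, edgeR 181 and 284, and DESeq2 1191 and 1460. The groups did not overlap in 64.0% of the tested genes, against 33.3% by chance. The numbers higher and lower were 1850 and 1718 without control A, 472 and 405 without control B, 30 and 39 without sgNrf2 tumour A and 25 and 33 without sgNrf2 tumour B. Leaving out 1 library leaves a lone sample in its group, which is assumed to vary like the other group. Genes called higher made up 43.1% of the calls, and 70.7% at equal totals, a scaling that moved the median of all genes from 0.04 to 0.34 and gave 874 genes higher and 362 lower. Relative to that median the NRF2 target genes were at 1.80, the ribosomal protein genes at -1.16 and the oxidative phosphorylation genes at -1.20. Since equal totals shift all genes nearly alike, these values restate the main fit and do not test the scaling. Quantile normalization gave 407 genes higher and 565 lower.

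**Figure D3:**
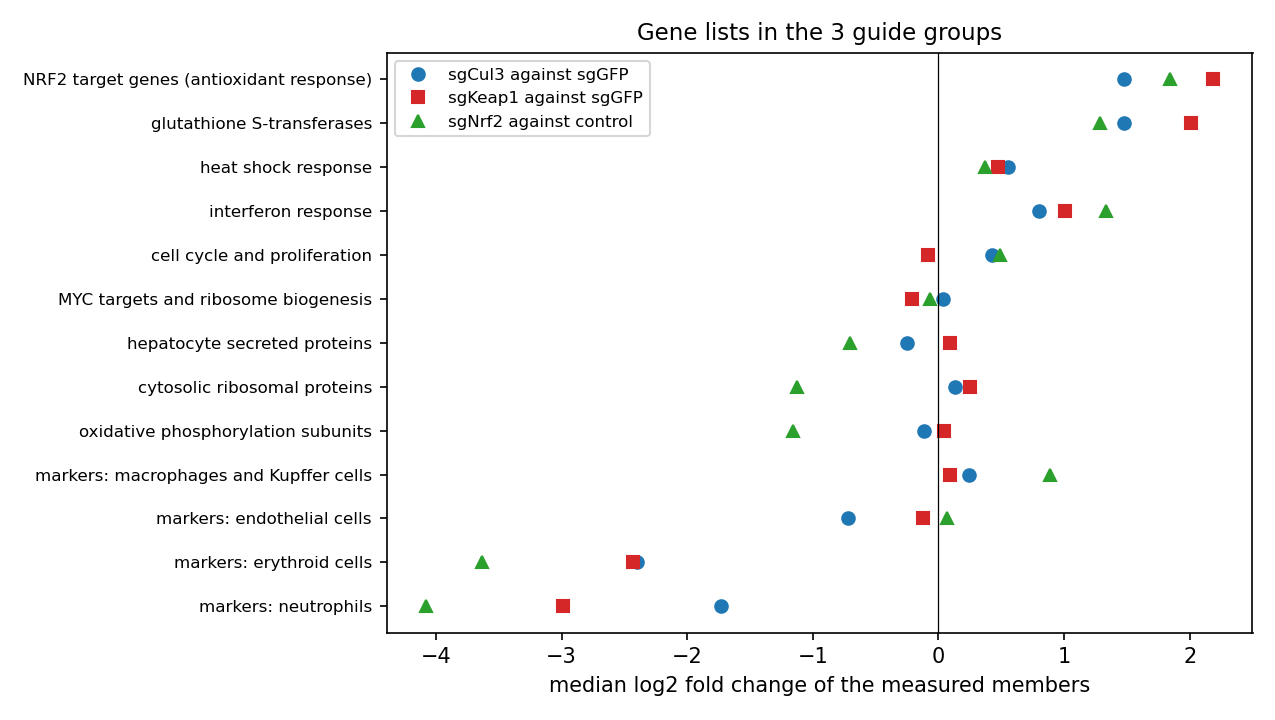
Median log2 fold change of the measured members of 13 gene lists in the sgCul3, sgKeap1 and sgNrf2 comparisons. The NRF2 target genes had medians of 1.47, 2.19 and 1.84, and the ribosomal protein genes 0.13, 0.25 and -1.13.

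Effects of the 3 guides were compared between the tables. Since controls A and B repeat sgGFP tumours 2 and 4, sgCul3 and sgKeap1 were set against sgGFP tumours 1 and 3 for this comparison. Levels in these still correlated at 0.959 between tumour 1 and control A and 0.960 between tumour 3 and control B. The 2 sets of controls are thus separate tumours but alike. Across 12847 genes, r with the sgNrf2 log2 fold changes was 0.357 for sgCul3 (rho 0.0954), 0.297 for sgKeap1 (rho 0.0219) and 0.340 for both together (rho 0.0603). Called in both with sgNrf2 were 22 genes higher and 5 lower for sgCul3, where independent calls would give 0.678 and 0.284. For sgKeap1 they were 78 and 24, where independent calls would give 4.30 and 2.61. For both together they were 60 and 17, where independent calls would give 2.67 and 1.11. With all 4 sgGFP tumours, 2 of them shared, r was 0.534, 0.442 and 0.513, and 70, 115 and 120 genes were higher and 35, 69 and 79 lower in both. With these 4, 97 genes passed in the same direction in all 3 comparisons, 64 higher and 33 lower. Among those with the largest changes, Gpx2, Slc5a4b, Slc7a11, Cbr3, Srxn1, Nqo1, Nrxn2 and Cyp7b1 were higher and Slc4a1, Sall4 and AF529169 lower. Cyp7b1 and Nrxn2 had 112 ± 33.7 against 1.84 ± 1.45 and 141 ± 59.8 against 1.33 ± 0.551 reads in sgCul3 and Sall4 2.71 ± 2.74 against 156 ± 58.0, log2 fold changes of 4.95 ± 0.42, 5.36 ± 0.40 and -5.17 ± 0.59 (adjusted p of 1.1e-04 to 0.0018).

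**Figure D4:**
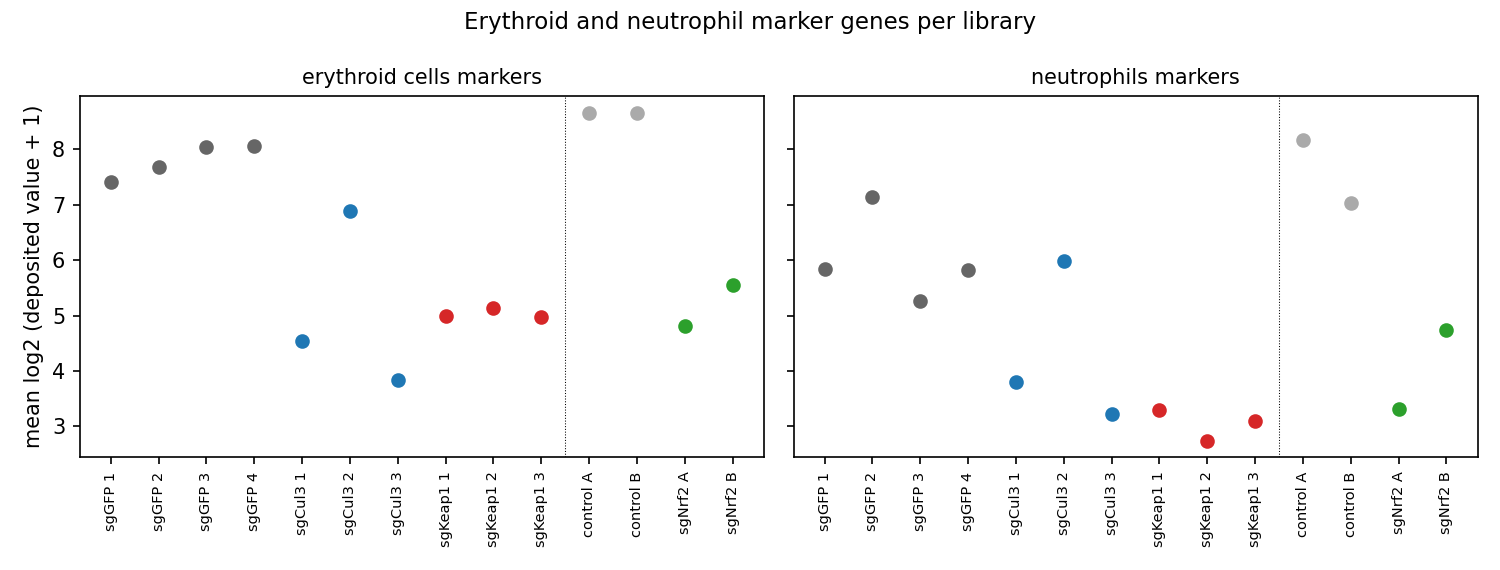
Mean log2 (deposited value + 1) of the erythroid and of the neutrophil marker genes in each library, with a dotted line between the separately scaled tables. Over both sets of markers the sgGFP tumours lay at 6.50 to 7.38, sgCul3 tumour 2 at 6.39 and the other sgCul3 and sgKeap1 tumours at 3.5 to 4.13.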

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

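The tests of fewer cells of every other type, also for the endothelial markers alone, of each set of blood markers alone, for the neutrophil markers in each guide group, and of sgKeap1 tumour 2, and the counts of other splits of the libraries, were chosen only after the result was seen.

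Among the sgGFP tumours, single libraries stood far from the other 3 for 6 of the named genes. Tumour 1 had 282 reads of Abcc4 against 34.9 to 61.4 in the others and 35.1 reads of Rec8 against 26.9 to 27.7. Tumour 2 had 3948 reads of Creb3l3 against 2594 to 2766, 81.3 reads of Elane against 21.6 to 28.3, 107 reads of Srxn1 against 47.2 to 56.4 and 1.53 reads of Gpx2 against 0. Of 82 groups tested, 6 held such a library, where chance gives 4.1.

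Effects of the Keap1 and Cul3 guides differed, by limma's test of sgKeap1 against sgCul3, for 8 genes. The log2 differences were 3.38 for Rec8, 1.82 for Kitl, 4.96 for Heph, -3.14 for Map2, -1.74 for Glipr2, -2.81 for Bsn and -2.77 for Fam169a. That of Ugt8a, fitted at 4.64, rests on few reads in sgCul3. Keap1 itself lay below every sgGFP tumour in the sgKeap1 tumours and above them all in the sgCul3 tumours, and the difference of -1.32 did not pass (limma adjusted p = 0.099). Reads that matched more than 1 gene were used in no comparison. Of all counts, those assigned to no gene included, they made up 0.638% and 0.614% in sgNrf2 tumours A and B. In controls A and B they made up 0.458% and 0.388%. Reads aligned to more than 1 place made up 45% and 46.4% in sgNrf2 against 56.8% and 58.0% in the controls. Reads on genes made up 47.6% and 46.0% against 34.7% and 33.2%. The difference in the first share may thus come from these other shares. It does not show more such reads per read on genes.

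The 78 ribosomal protein and oxidative phosphorylation genes had a median log2 fold change of -1.14 in sgNrf2. With the trend of all genes on GC content removed it was -1.15 (-1.32 to -0.91), which argues against GC content as the cause. With the trend on transcript length removed it was -0.60 (-0.71 to -0.46), which leaves length open. Since length was that of the longest annotated transcript, not of the one expressed, the test cannot decide between part and whole of the cause. With the trend on level removed it was -0.92 (-1.13 to -0.65), an interval that leaves a part for level open. In the other table the same genes were higher in sgGFP tumours 2 and 4, whose repeats are the controls of sgNrf2, than in tumours 1 and 3 by a median of 0.53 (0.37 to 0.64), so the choice of control tumours could account for part of the difference. An effect of the ETGE guide also stays open and, with 2 tumours, cannot be told apart from these.

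Neutrophil and erythroid markers, none of them on another list, had negative medians with each guide, as in Hbb-bs (2694 to 8215 reads in sgGFP, 7688 in sgCul3 tumour 2 and 261 to 1439 in the other guide tumours of that table) and S100a8 (203 to 1768, 1159 and 43.0 to 135). The macrophage, endothelial and stellate markers were at -0.0393 (-0.14 to 0.13) for both guides together, where the blood markers were at -2.39. They were at 0.65 (0.23 to 0.87) in sgNrf2, where the blood markers were at -3.68. These pooled values argue against fewer cells of every other type, with intervals over genes, not tumours. In sgNrf2 limma called 0 macrophage markers higher and 2 lower. It called 4 stellate markers higher and 0 lower, and 1 endothelial marker higher and 0 lower. The pooled value there leaves fewer macrophages open. The endothelial markers alone were at -0.47 (-0.86 to -0.15) for both guides (-0.55 to -0.32 with 1 library left out) and at -0.72 (-1.17 to -0.55) in sgCul3 (-0.87 to -0.52), which leaves fewer endothelial cells open. Over both sets of blood markers 4 of the 4 sgGFP tumours lay above every guide tumour of the table (6.50 at the lowest against 6.39 in sgCul3 tumour 2). That margin is narrow and the 2 sets differ in sgCul3, so the pooled level cannot decide on blood-rich controls. For the erythroid markers alone 4 lay above too (7.40 against 6.89), which argues against 1 or 2 blood-rich controls for these. The neutrophil markers in sgKeap1 do so as well, with 4 above every sgKeap1 tumour (5.27 against 3.29). For the neutrophil markers in sgCul3 it was 1, sgGFP tumour 2. The other 3 sgGFP tumours, at 5.27 to 5.84, lay below sgCul3 tumour 2 at 5.99. All 4 sgGFP tumours lay above sgCul3 tumours 1 and 3, at 3.8 and 3.22. The count of 1 thus rests on 1 sgCul3 tumour and cannot decide on blood-rich controls there. Fewer neutrophils and red cell precursors in tumours with active NRF2 may be a source too. So may the blood left in each tumour, on which the labels, which name no sort, are silent.

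Tumour 2 of sgKeap1 had a mean correlation of 0.851 with the other libraries of its table, against 0.892 to 0.924 in the deeper ones. Low depth alone is argued against by the 0.920 of another library of like depth, sgKeap1 tumour 3, and an sgGFP tumour under this label by 38 of 49 NRF2 target genes lying above all 4 sgGFP tumours, where chance gives 9.8. An sgCul3 tumour under this label is argued against by the 7 genes called between sgKeap1 and sgCul3 without it, since it lay nearer to the mean of sgKeap1 tumours 1 and 3 in 6, all but Limk1, and by its 414 reads of Keap1, below the 823 to 1149.5 of the sgCul3 tumours, though its r was highest with sgCul3 tumour 2 (0.922, against 0.892 and 0.911 with its own group) and its 596 reads of Cul3 lay within their 163 to 676. Against the mean of sgKeap1 tumours 1 and 3, 101 genes of secreted proteins, the urea cycle and P450 enzymes were at a median of 1.80 (1.45 to 2.09) and 44 cell cycle genes at -0.29 (-0.43 to -0.13), and normal liver in the sample could raise the first and lower the second. The cell cycle difference is too small to decide, and a tumour closer to mature liver cannot be told apart from it.

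The libraries were also divided in other ways into groups of the same sizes. For sgKeap1 against sgGFP, 1 of 35 splits, the real one, gave as many as the 1020 called genes, and the highest other gave 1. For both guides together 32 splits part all 3 same-numbered pairs of sgGFP and sgCul3 tumours, of which 1, the real one, gave the 986 genes, and in the highest other limma called 0 (1280 at most at an unadjusted p under 0.05). Of 100 splits drawn without regard to the pairs the highest other gave 460, with sgGFP tumour 4 and sgCul3 tumour 3 exchanged, which parts 2 of the pairs. For these 2 counts no other split gave as many genes, which is 1 in 35 and 1 in 32, the lowest shares these splits allow. Splits that mix guide and control tumours put the guide effect into the spread within groups, which lowers their counts. The splits therefore cannot exclude chance division. For sgCul3 against sgGFP, where the numbers were taken to pair the tumours, 8 of the 35 splits part all 3 pairs, too few for a share under 0.05. Of these 1, the real one, gave the 287 genes, and in the highest other limma called 0 (1441 at most at an unadjusted p under 0.05), while those that part 0, 1 or 2 pairs gave at most 53, 2 and 10. For sgKeap1 against sgCul3 the 10 splits, of which 1 reached the real 8, are too few for a share under 0.05, and the highest other gave 1.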

How the results depend on the processing

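Removing the added 1, testing lists without 1 library or with the block and counting NRF2 target genes under each alternative were chosen only after the data were seen. In the order sgCul3, sgKeap1, both guides together, sgKeap1 against sgCul3 and sgNrf2, 395, 568, 267, 129 and 368 of 408, 575, 269, 148 and 374 checks of named genes kept direction and side of the threshold under the settings other than left-out libraries, 10, 7, 0, 17 and 5 lost the call, 3, 0, 2, 2 and 1 gained it and 0 changed direction. With 1 library left out, 249, 392, 298, 60 and 150 of 287, 406, 300, 90 and 187 checks kept both, and 0 changed direction. Counts of called genes stayed within 1.5 times the reported ones under the alternatives not named here. DESeq2 called 479 and 447 genes higher and lower in sgCul3, 1181 and 962 in sgKeap1, 1105 and 947 for both guides, 64 and 40 for sgKeap1 against sgCul3 and 1191 and 1460 in sgNrf2. Among genes with a mean of at least 50, fewer genes tested, 115 and 47 passed in sgCul3 and 2 were higher in sgKeap1 against sgCul3. With the 2 groups tested alone, fewer samples, limma called 96 and 72 in sgCul3 and 0 and 0 for sgKeap1 against sgCul3, where 1164 had an unadjusted p under 0.05, edgeR called 3 and 3 and DESeq2 64 and 40 with all groups. Equal totals gave 365 higher in sgKeap1 and 874 in sgNrf2, quantile normalization 407 and 565 in sgNrf2. For DESeq2 and these scalings the cause was not tested. With the tumour number as a block, 975 and 803 genes passed in sgKeap1, 146 and 86 in sgCul3, 689 and 523 for both guides, 5 and 4 for sgKeap1 against sgCul3 and 300 and 383 in sgNrf2, and the cause was not tested. For sgCul3 and for both guides together, other than beside the results, the block changed no call of a described gene and no camera call of a described list, and it moved the counts of their members by at most 1.5 times (in sgCul3 to 25 NRF2 target genes, 11 glutathione S-transferases, 3 bile acid synthesis genes and 4 erythroid markers). Between the other groups not every correlation was over 0.1, so the numbers were not taken to pair those tumours. The deviations of same-numbered libraries correlated at 0.199, 0.0425 and -0.0941 between sgGFP and sgKeap1 and at -0.000641 in the second table. Between sgCul3 and sgKeap1 they correlated at 0.239, 0.518 and 0.0980, the last just under 0.1, so pairing of these tumours stays open. Not every library correlated best with its own number. In the comparisons not taken as paired, the adjusted p with the block was 0.063 for Keap1 and 0.060 for Xist in sgKeap1, and 0.070 for Fam169a, 0.064 for Heph, 0.061 for Map2 and 0.061 for Ugt8a in sgKeap1 against sgCul3. With 1 library left out, the genes higher numbered 44 to 212 (sgCul3), 201 to 814 (sgKeap1), 257 to 882 (both guides together), 0 to 6 (sgKeap1 against sgCul3) and 25 to 1850 (sgNrf2), and the genes lower 21 to 116 (sgCul3), 113 to 688 (sgKeap1), 138 to 671 (both guides together), 0 to 3 (sgKeap1 against sgCul3) and 33 to 1718 (sgNrf2). Camera called 15, 16, 16, 15 and 19 lists, 14 to 22, 12 to 19, 13 to 23, 10 to 21 and 17 to 22 with 1 library left out, and 0 in each comparison with an estimated correlation (4, 4, 5, 0 and 1 of the called lists at an unadjusted p under 0.05, and 5, 9, 8, 0 and 0 lists called by fry). Separate controls, fewer samples each, gave 22 to 90 genes higher and 8 to 44 lower in both guides. With all 4 sgGFP tumours, more samples, 70 genes were higher and 35 lower in both sgCul3 and sgNrf2, and 69 lower in both sgKeap1 and sgNrf2. The NRF2 target genes that rose numbered 15 to 31 in sgCul3, 31 to 39 in sgKeap1, 32 to 37 for both and 18 to 30 in sgNrf2 under the alternatives, and 12 to 21, 27 to 33, 30 to 36 and 8 to 25 with 1 library left out. In simulated data of the same size, 3.09, 4.12, 18.4, 0 and 0% of genes changed 2-fold passed, and 60.6, 51.0, 78.1, 46.5 and 25.5% of those changed 4-fold, and 10.4, 11.5, 5.10, 6.12 and 19.4% of the calls were false, so changes near 2-fold were mostly not detectable at this number of tumours.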

Other observations

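Counts, medians and tests of lists without 1 library or with the block were added only after the results were seen. Genes of the interferon response had positive medians with each guide. In sgCul3 1 of 32 rose, or 2 rose and 1 fell adjusted over the list alone, at a median log2 fold change of 0.80 (camera adjusted p = 0.0023, or adjusted p = 0.79 with an estimated correlation). In sgKeap1 2 of 32 rose, or 2 adjusted over the list alone, at a median of 1.01 (camera adjusted p = 0.0033, or adjusted p = 0.86 with an estimated correlation), but of 0.27 without sgKeap1 tumour 2, in which 32 of the 32 lay above the mean of tumours 1 and 3, by a median of 1.74. In sgNrf2 3 of 32 rose, or 15 rose and 2 fell adjusted over the list alone, at a median of 1.33 (camera adjusted p = 1.4e-04, or adjusted p = 0.69 with an estimated correlation), among them Ifi27 (1.79 ± 0.30). Of the interferon genes in sgCul3, 0 (3 at an unadjusted p under 0.05) rose without sgGFP tumour 3 or sgCul3 tumour 2 and 0 (7 at an unadjusted p under 0.05) without sgCul3 tumour 1. Of the interferon genes in sgKeap1, 1 rose without sgGFP tumours 1, 2, 3 or 4 or sgKeap1 tumours 2 or 3. Of the interferon genes in sgNrf2, 0 (6 at an unadjusted p under 0.05) rose without sgNrf2 tumour B, 0 (11 at an unadjusted p under 0.05) without sgNrf2 tumour A, 5 without control B and 18 without control A. In camera the interferon genes in sgCul3 did not pass without sgCul3 tumour 2 (adjusted p = 0.17). Interferon genes in sgCul3 had a median of 0.40 without sgCul3 tumour 2. In camera the interferon genes in sgKeap1 did not pass without sgKeap1 tumour 2 (adjusted p = 0.22).

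Of the male-biased genes of mouse liver, 2 of 11 rose, or 2 adjusted over the list alone in sgCul3, at a median of 0.53 (camera adjusted p = 0.026, or adjusted p = 0.79 with an estimated correlation). In sgKeap1 1 of 11 rose, or 4 adjusted over the list alone, at a median of 1.06 (camera adjusted p = 0.034, or adjusted p = 0.85 with an estimated correlation), and in sgNrf2 3 of 11 rose, or 7 rose and 1 fell adjusted over the list alone, at a median of 1.68 (camera adjusted p = 0.0016, or adjusted p = 0.69 with an estimated correlation). Cyp7b1, which is also on the bile acid list, passed in each of these. Gstp1 (1.95 ± 0.29) rose in sgCul3, and Gstp1 (2.18 ± 0.23) and Serpina1e (2.71 ± 0.26) rose in sgNrf2. Gstp1 is also on the list of glutathione S-transferases, so the 2 male-biased genes that rose in sgCul3 both belong to other lists as well. The female-biased genes did not pass as a list, with medians of -0.69, -0.22 and -1.45 (camera adjusted p = 0.083, 0.78 and 0.19). The labels do not give the sex of the mice. Xist, expressed from the inactive X chromosome, had 6235, 9563, 9225 and 11476 reads in the sgGFP tumours, 5290.3, 2856 and 4275 in sgCul3 and 4000.4, 3087 and 5459 in sgKeap1, and 18199 and 25068 in controls A and B against 9423 and 10924 in sgNrf2. Its log2 fold changes were -1.15 ± 0.30, -1.13 ± 0.30 and -1.07 ± 0.26 (limma adjusted p = 0.080, 0.045 and 0.078). The adjusted p of Xist was 0.083, 0.11 and 0.077 without sgGFP tumours 2, 3 or 4, 0.068, 0.17 and 0.071 without sgKeap1 tumours 1, 2 or 3, 0.054 with edgeR and 0.054 with the 2 groups tested alone, in a range of 0.0043 to 0.17 over its alternatives. Of the cell cycle genes, 3 of 44 rose, or 5 adjusted over the list alone in sgCul3, among them Ccne1 (1.0 ± 0.23) and Cdk1 (0.87 ± 0.20), at a median of 0.43 (camera adjusted p = 2.5e-07, or adjusted p = 0.77 with an estimated correlation). In sgKeap1 1 of 44 rose and 1 fell, or 1 adjusted over the list alone, at a median of -0.08, -0.20 to 0.01 with 1 library left out (camera adjusted p = 0.90, or adjusted p = 0.98 with an estimated correlation), and in sgNrf2 2 of 44 rose, or 4 adjusted over the list alone, among them Hmmr (1.23 ± 0.19), at a median of 0.49 (camera adjusted p = 5.9e-04, or adjusted p = 0.69 with an estimated correlation). Of the male-biased genes in sgKeap1, 2 rose without sgKeap1 tumour 2. Of the male-biased genes in sgNrf2, 1 rose without sgNrf2 tumours A or B and 5 without control A. In camera the male-biased genes in sgCul3 did not pass without sgGFP tumour 1 or sgCul3 tumour 2 (adjusted p = 0.064 and 0.26). Male-biased genes in sgCul3 had a median of 1.09 without sgCul3 tumour 1 and 0.34 without sgCul3 tumour 2. In camera the male-biased genes in sgKeap1 did not pass without sgGFP tumours 1 or 2 or sgKeap1 tumour 2 (adjusted p = 0.054, 0.057 and 0.20). Male-biased genes in sgNrf2 had a median of 0.98 without sgNrf2 tumour A. In camera the female-biased genes in sgCul3 passed without sgGFP tumour 1 or sgCul3 tumour 2 (adjusted p = 0.013 and 0.0096). In camera the female-biased genes in sgNrf2 passed without sgNrf2 tumours A or B (adjusted p = 0.048 and 0.043). Of the cell cycle genes in sgCul3, 1 rose without sgGFP tumours 1, 2, 3 or 4 or sgCul3 tumours 1 or 2. Of the cell cycle genes in sgKeap1, 3 rose without sgKeap1 tumour 1. Of the cell cycle genes in sgNrf2, 0 (3 at an unadjusted p under 0.05) rose without sgNrf2 tumour B, 1 without sgNrf2 tumour A and 18 without control A. Of the cell cycle genes in sgKeap1, 0 (2 at an unadjusted p under 0.05) fell without sgGFP tumour 1 or sgKeap1 tumour 2, 0 (3 at an unadjusted p under 0.05) without sgGFP tumour 3, 0 (5 at an unadjusted p under 0.05) without sgGFP tumour 2 and 0 (6 at an unadjusted p under 0.05) without sgKeap1 tumour 3. With the tumour number as a block, 1 of the cell cycle genes rose in sgCul3.

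Controls A and B lay closest to the tumours they are labelled as repeating. Across 12905 genes Pearson's r was 0.992 between control A and sgGFP tumour 2 and 0.979 between control B and sgGFP tumour 4, against 0.887 to 0.960 with the other sgGFP tumours. Genes are not independent replicates.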
